A study of Mus musculus with 10 samples.

How the data were processed

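Peak lists of 6 CUT&Tag libraries from mouse macrophages were analysed, 4 with an antibody against NPM1 and 2 with one against H3K4me3, each the only library of its group. Per the labels' protocols, libraries were made with a commercial hyperactive transposase kit and amplified for Illumina sequencing. Per the submitters' processing notes, bcl2fastq 2.17, Bowtie2, MACS2 2.2.7.1 and deepTools were used and the genome build was mm10. The settings of these tools, the handling of duplicate reads, the use of a control library and any spike-in are not given in the sources used here.

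Each deposited file is a narrowPeak list called on 1 library, with a position, a score, a fold enrichment, a −log10 p, a −log10 q and a summit per peak. The smallest deposited −log10 p was 2.01 and the smallest width 200 bp. Between 5.01% and 27.8% of the peaks of a list had a deposited q above 0.05. The deposited score equals 10 times the −log10 p, to within 1, in all peaks. The deposited fold enrichment is the ratio of the pileup at the summit to the local background, each with 1 added. The −log10 p and −log10 q were deposited by the authors as MACS2 wrote them. No peaks of a list overlapped, so each peak was a region.

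Depth was read from the peak values. The fold and the −log10 p at a summit fix a whole-number pileup and a background, found within 0.001 for 99.8% to 99.9% of the summits of each list, and the most frequent background was taken as the genome-wide one. In all 6 lists the local backgrounds were within 0.001 of multiples of 0.02, as unscaled reads extended to 200 bp and averaged over 10 kb would give. At a given enrichment, q grows with depth. Fold and q were used to rank and filter the peaks of each list. Where values of 2 lists, or counts past the same threshold, stand side by side, they also differ with the depth and enrichment of the whole libraries and do not measure a change at a gene. Counts and shares of peaks are of called peaks, and the absence of a peak means that none was called at that depth.

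Genes were the 21887 protein-coding genes on assembled chromosomes of the GRCm38.p6 gene table, the assembly that mm10 names. The table gives the outermost start and end of each gene and neither strand nor transcripts. The plan had been to use windows around any transcription start site, so the window became the 1 kb on either side of both gene ends, and exons, introns and UTRs could not be told apart. Promoters that lie inside a gene's outermost extent are missed. Positions are 1-based. All numbers were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

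For each pair of libraries the genes with a gene-end peak in the first only, the second only and both were counted, beside the number that independent lists would share, and regions were called shared with an overlap of 1 bp or more. Random expectations came from 100 placements of the peaks of a list at random within their chromosomes, without regard to mappability. For 21 gene lists fixed before the data were examined, and for the olfactory receptor genes, the net change was the number of genes in 1 library only minus that in the other, over the genes in either. Its percentile was taken among 10000 random lists matched on the fifth of the higher fold of the 2 libraries. Of 405 listed genes, 2 were not protein-coding in the table, the interferon genes Mx1 and Mx2. The lists cover mTORC1 and TSC signalling, H3K4 methylation enzymes, metabolism, macrophage states and identity, proliferation, ribosomes, housekeeping, other cell types of the heart and silent tissue genes.

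Genes were named by a rule fixed before the data were examined. Npm1, Kdm5b, Tsc1, Tsc2 and Mtor are given in every comparison. For each direction of a pair the 8 genes with the highest −log10 q and no peak within 5 kb in the other library are given, passing over predicted, olfactory and vomeronasal genes and genes sharing a peak with one already taken. From each list up to 3 members per direction and examples with both are given. For NPM1 with H3K4me3, 8 genes with and 5 without the mark are given. Further members of a list and genes shared across comparisons are named to complete a count.

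The code was tested on simulated peak lists for a pair of libraries, where 400 of 400 genes planted in the compared list only, 200 of 200 in the reference list only and 300 of 300 in both were recovered, as were 5000 of 5000 simulated pileups. The alternatives were stricter peaks by q or by fold, equal list lengths, autosomes only, other windows, summits in the window, reciprocal overlap, stitched peaks and unmatched random lists. After the data were seen, the H3K4me3-marked gene end, thinning of the deeper list to the shallower background, peaks with q of 0.05 or less, list counts with −log10 q of 5 or more, alternatives for H3K4me3 covered bases and other matchings of 1 gene list were added. No test across samples was possible with 1 library per group.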

Results

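CUT&Tag, which cuts and tags DNA where an antibody sits on chromatin, was used to map nucleophosmin (NPM1), a histone chaperone of the nucleolus and nucleoplasm, and histone H3 trimethylated at lysine 4 (H3K4me3), a mark of active promoters, in mouse macrophages. The series held 10 libraries, 1 per group, and the peak lists of 6 were analysed here. NPM1 was mapped in wild-type (WT) cardiac macrophages isolated at day 3 from sham-operated and from infarcted hearts. It was also mapped in WT bone marrow-derived macrophages (BMDM), grown for 7 days with 50 ng/ml M-CSF, that were left untreated or received 20 ng/ml interleukin-4 (IL-4) for 12 hours. H3K4me3 was mapped in WT and in Npm1 conditional-knockout cardiac macrophages at day 3 after infarction. The other 4 libraries, H3K4me3 and a target labelled K5 in IL-4-treated BMDM of both genotypes, were not analysed here. With 1 library per group, no difference below has a replicate check and no p-value is given.

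The lists held 58011 peaks for NPM1 in sham macrophages and 79893 after infarction, 58989 in untreated BMDM and 104514 with IL-4, and 73321 for H3K4me3 in WT and 52977 in knockout macrophages. Total reads were not given, but the peak values carry the genome-wide background pileup, which scales with depth. It was 1.29 reads per position for sham, 3.03 for infarct, 1.31 for untreated, 4.18 for IL-4, 2.92 for WT H3K4me3 and 2.49 for knockout H3K4me3. A gene was counted as having a gene-end peak where a peak overlapped the 1 kb on either side of an annotated end of a protein-coding gene. The annotation at hand gave no strand, so the promoter end could not be separated from the other end. Fold enrichment and −log10 q are the authors' values for each peak and rank peaks within a list. Values of different lists printed side by side do not measure a change.

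NPM1 in infarct and in sham cardiac macrophages was compared to ask where NPM1 occupies the genome after injury. After infarction, 11072 of 21887 protein-coding genes had an NPM1 gene-end peak, against 2384 in the sham library. Of these, 9509 genes had a peak in the infarct library only, 821 in the sham library only and 1563 in both, where independent lists would share 1206. For any pair of lists, genes counted in both can have their peaks at different ends, as Tsc1 did here. With −log10 q of 5 or more the counts of infarct only, sham only and both were 6009, 58 and 91. The H3K4me3-marked end is that with the higher H3K4me3 fold in either H3K4me3 list. There the counts were 9112, 290 and 723, without the 7554 genes that had no H3K4me3 gene-end peak. Random placement of the peaks of each list marked a mean of 3032 genes for infarct and 2081 for sham. All 30 measured genes of mTORC1 and TSC signalling, the pathway that couples nutrients to growth, had a peak after infarction, against 4 in sham. Macrophage identity genes (21 against 1 of 23), glycolysis genes (17 against 1 of 21) and ribosomal protein genes (31 against 4 of 32) were marked in the same direction. A −log10 q of 5 or more was reached at 6100 genes in infarct and 149 in sham. At that threshold the mTORC1 and TSC list had 19 genes, macrophage identity 12, glycolysis 14 and ribosomal proteins 21, against 0 in sham.

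Npm1 itself (chromosome 11, 33152498 to 33164142, mm10) had an NPM1 peak at its gene end in the infarct library, with a fold of 7.14 and −log10 q of 16.8, and none in sham. Tsc1, the hamartin gene whose product restrains mTORC1 (chromosome 2, 28640993 to 28691172), carried an infarct peak of 1065 bp over its first annotated end, from 28640640 to 28641704, with a fold of 6.17 and −log10 q of 16.1. The sham list had no peak there and a 212 bp peak inside the other end of Tsc1, with a fold of 4.81 and −log10 q of 3.60. Mtor, the kinase gene (chromosome 4, 148448582 to 148557685), had an infarct peak with a fold of 3.68 and −log10 q of 4.15 and no sham gene-end peak. Tsc2, the tuberin gene on chromosome 17, had weak peaks in both lists just outside the end opposite to its H3K4me3, with −log10 q of 2.05 in infarct and 1.36 in sham. Kdm5b, an H3K4 demethylase gene on chromosome 1, had no NPM1 gene-end peak in either list.

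**Figure D1:**
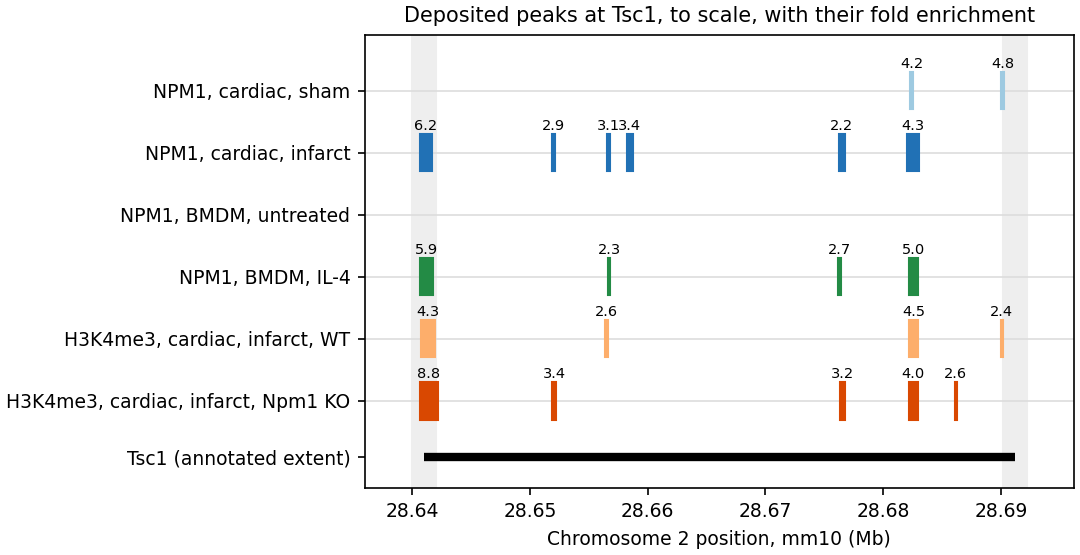
Deposited peaks of the 6 libraries across Tsc1 on chromosome 2 (horizontal axis, mm10 position in Mb), each drawn to scale with its fold enrichment above it. The grey bands are the 1 kb on either side of the annotated gene ends. The band at 28640993 holds peaks of the infarct and IL-4 NPM1 libraries and of both H3K4me3 libraries, and none of the sham or untreated NPM1 libraries.

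Among the genes with an infarct peak and no sham peak within 5 kb, the highest −log10 q belonged to Wee1, a kinase gene of the G2 checkpoint, with a fold of 13.6 and −log10 q of 115. Ubxn6, Malt1, an adaptor of NF-kappaB signalling, Tle4, a transcriptional corepressor, Rnf149, Rnft1, Hspa8, a constitutive heat shock chaperone, and Amz2 followed, with −log10 q from 106 down to 74.6. In the mTORC1 and TSC list the strongest infarct-only peaks lay at Akt1s1, Lamtor1 and Rragc, with folds of 5.38, 7.03 and 7.61. In glycolysis they lay at Pgam1, Pkm and Hk2, with folds of 7.71, 5.81 and 8.13. In the tricarboxylic acid cycle and oxidative phosphorylation list 19 of 21 genes had an infarct peak against 3 in sham, led by Mdh2, Cs and Ogdh, and in fatty acid oxidation 14 of 15 against 2, among them Etfdh and Cpt1a.

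Of the 24 IL-4 response genes, 12 had an infarct peak and 3 a sham peak. Of all genes, 50.6% had an infarct and 10.9% a sham peak. Pparg, a lipid-sensing nuclear receptor, and Socs1 and Klf4 had the strongest infarct-only peaks, with folds of 6.28, 4.42 and 4.50. Inflammatory macrophage genes were marked too, 17 of 26 against 2, among them Cxcl2 with a fold of 7.68. Ccl3 and Ccl4 shared 1 peak with a fold of 5.79. Reparative macrophage genes (16 against 3 of 22) included Axl, Fabp5 and Lgals3 in infarct only and, with −log10 q of 0.863, Folr2 in sham only. The infarct peak of Axl lay wholly outside the gene, before its first annotated end. Interferon response genes (9 against 2 of 14) included Stat2 in infarct only. Oas1a and Ifit3 had peaks in sham only, with −log10 q of 4.42 and 1.38. Macrophage identity genes with an infarct-only peak included Ctsb and Cd68, with folds of 5.63 and 4.18. Ribosome biogenesis (21 against 1 of 22), proliferation (17 against 1 of 17), H3K4 methylation enzymes (13 against 2 of 16) and housekeeping genes (16 against 1 of 19) had the same direction. With −log10 q of 5 or more, interferon response genes numbered 1 against 0, IL-4 response 6 against 0, inflammatory 12 against 0 and reparative 10 against 2. Ribosome biogenesis genes then numbered 16, proliferation 8, H3K4 methylation enzymes 7 and housekeeping 13, against 0 in sham.

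Of the markers of other cells, an infarct peak was found at 4 of 20 cardiomyocyte, 3 of 14 fibroblast, 6 of 13 endothelial, 4 of 12 neutrophil, 3 of 14 T and NK cell and 2 of 10 B cell genes, against 2, 1, 1, 1, 1 and 1 in sham. With −log10 q of 5 or more, each of these lists had at most 1 marked gene in infarct and 0 in sham. Of 18 silent tissue genes, 4 had an infarct and 2 a sham peak, and of 1110 olfactory receptor genes, 42 and 64. Relative to all genes with a peak, the macrophage identity list lay at percentile 98.2 of the net change of 10000 matched random lists and olfactory receptors at 0, while the other 20 lists lay within the central 95% of random lists. The sham-only genes were headed by Dpy19l3, with a fold of 7.44 and −log10 q of 9.82, then Exosc10, Mdga1, Krtap6-2, Oxct2b, Crisp4, Crnn and Nlrp4c, with −log10 q down to 5.37. Krtap6-2, of the hair keratin-associated proteins, and Nlrp4c belong to families of similar genes.

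The infarct background was 2.35 times that of sham. Whole peak lists differed in another way from gene ends. No counterpart was found for 63579 infarct and 41367 sham regions, and 20.4% of infarct regions were shared against 1.55% for random placements. With infarct summits thinned to the sham background, the unshared regions numbered 41908 and 45682. Thinning only removes called infarct peaks and adds none, so that order does not settle gain or loss. Of sham peaks 3.61% had their midpoint within 1 kb of a gene end, 40.1% elsewhere in genes and 56.3% outside, against 14.3%, 44.7% and 41.0% of infarct peaks.

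**Figure D2:**
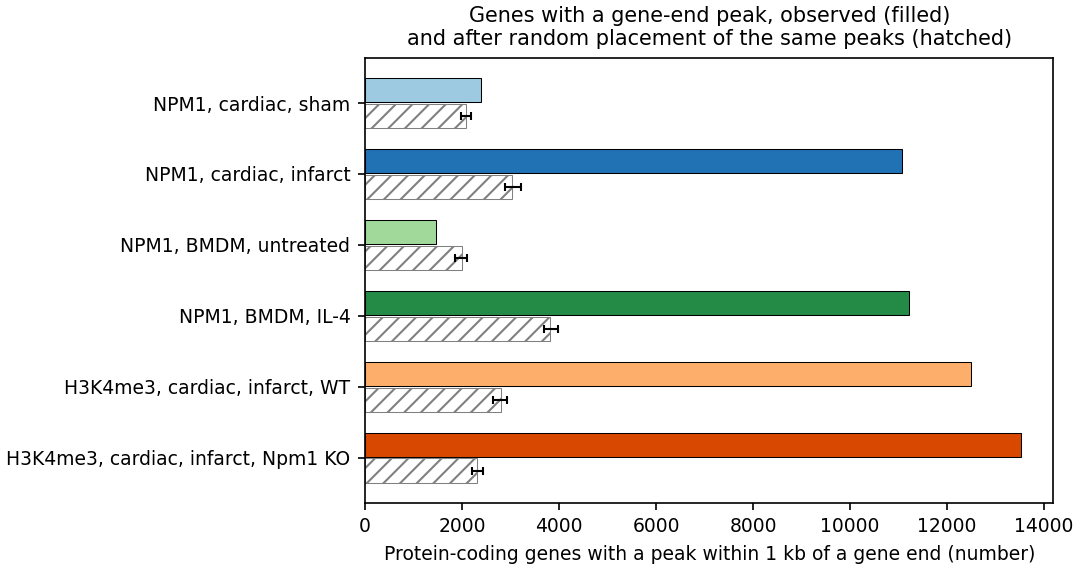
Number of protein-coding genes with a gene-end peak (horizontal axis) in each of the 6 libraries (filled bars), beside the mean of 100 random placements of the same peaks within chromosomes (hatched bars, whiskers from the lowest to the highest placement). The sham NPM1 library had 2384 genes against a random mean of 2081 and the untreated library 1469 against 2007, while the infarct library had 11072 against 3032.

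NPM1 in IL-4-treated and in untreated BMDM was compared to ask whether a reparative stimulus in culture gives a similar occupancy. With IL-4, 11214 genes had an NPM1 gene-end peak, against 1469 in untreated cells. Random placement of the peaks of each list marked a mean of 3817 and 2007 genes, so the untreated list lay below its random mean. A peak was found in the IL-4 library only at 10179 genes, in the untreated library only at 434 and in both at 1035, where independent lists would share 753. With −log10 q of 5 or more these counts were 6356, 16 and 71. At the H3K4me3-marked end, again without the genes lacking an H3K4me3 gene-end peak, they were 9061, 111 and 707. The mTORC1 and TSC list had 27 of 30 genes marked with IL-4 against 4, macrophage identity 21 of 23 against 1 and ribosome biogenesis 21 of 22 against 1. The IL-4 response list had 12 of 24 marked genes against 0. With IL-4 that is about the share of all genes, 51.2%, and 6.71% of all genes were marked in untreated cells. A −log10 q of 5 or more was reached at 6427 genes with IL-4 and 87 in untreated cells. At that threshold mTORC1 and TSC had 19 genes, macrophage identity 14, ribosome biogenesis 16 and IL-4 response 8, against 0 in untreated cells.

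Npm1 had an IL-4 peak with a fold of 5.46 and −log10 q of 12.3 and none in untreated cells. Tsc1 had an IL-4 peak of 1081 bp, from 28640650 to 28641730, with a fold of 5.93 and −log10 q of 20.9, and the untreated list had no peak in or within 1 kb of Tsc1. Mtor had an IL-4 gene-end peak with a fold of 4.33 and −log10 q of 7.26 and no untreated one. Kdm5b and Tsc2 had no gene-end peak in either list. The leading IL-4-only genes were Plekho1, Gatad2a, a NuRD complex subunit, Rnft1, Slc37a4, a glucose-6-phosphate transporter, Ccdc9, Pknox1, Rnf149 and Tbl2, with folds from 9.94 to 15.1 and −log10 q from 111 down to 89.6. Rnft1 and Rnf149 were also among the leading infarct-only genes.

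Within the IL-4 response list, Socs1, Klf4 and Irf4, a transcription factor induced by IL-4, had the strongest IL-4-only peaks, with folds of 5.21, 4.90 and 5.98. Arg1, Retnla, Ccl22 and Ccl24, picked from this list after their values were seen, had no NPM1 gene-end peak in any of the 4 NPM1 lists. Inflammatory genes were marked at 17 of 26 with IL-4 against 0, led by Tnf, Cxcl2 and Ccl3 with folds of 5.60, 7.41 and 7.40. Reparative genes were marked at 18 of 22 against 1, led by Axl, Fabp5 and Il10. The Axl peak lay wholly outside the gene, before its first annotated end, as it did after infarction. Interferon response genes were marked at 10 of 14 against 0, led by Stat2. With −log10 q of 5 or more, inflammatory genes numbered 11, reparative 11 and interferon response 3, against 0 in untreated cells. In glycolysis 17 of 21 genes were marked against 3, led by Pgam1, Hk2 and Pkm with folds of 7.74, 7.70 and 5.79. The tricarboxylic acid cycle and oxidative phosphorylation list had 20 of 21 against 3, with Mdh2 first, and fatty acid oxidation 13 of 15 against 1.

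Eif4ebp1 and Akt1s1, targets of mTORC1, had IL-4-only peaks with folds of 6.44 and 5.38, while Rragd and Lamtor2 had peaks in both lists. Ctsb, Cebpa and Tyrobp led the macrophage identity list, with folds of 6.13, 6.41 and 5.92. H3K4 methylation enzymes were marked at 13 of 16 against 0, led by Kmt2a with a fold of 9.01, proliferation genes at 16 of 17 against 2, ribosomal protein genes at 31 of 32 against 2 and housekeeping genes at 16 of 19 against 2. With −log10 q of 5 or more they numbered 8 against 0, 9 against 0, 24 against 0 and 13 against 1. Of the markers of other cells, an IL-4 peak was found at 8 of 20 cardiomyocyte, 4 of 14 fibroblast, 6 of 13 endothelial, 5 of 12 neutrophil, 6 of 14 T and NK cell and 2 of 10 B cell genes, with at most 1 in any of these lists in untreated cells. With −log10 q of 5 or more, each had at most 2 marked genes with IL-4, cardiomyocytes 1, and 0 in untreated cells. Of 18 silent tissue genes, 7 had an IL-4 peak, among them Prm1 with a fold of 9.08, and 1 an untreated peak, and olfactory receptors numbered 46 and 35 of 1110. Only the olfactory receptors, at percentile 0, lay outside the central 95% of random lists for the net change. Some lists had the highest possible net change, 100%, and still lay inside, such as inflammatory genes at 95.4 and IL-4 response at 90.1. For such lists this percentile could not show an excess.

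The untreated-only genes were led by Sema5b, a semaphorin gene, with a fold of 6.61 and −log10 q of 7.53, then Dsg4, Krtap5-3, Adgra2, Acmsd, Calhm4, Chil5 and Ctxn3, with −log10 q down to 3.47. Krtap5-3 and Chil5 belong to families of similar genes. The IL-4 background was 3.18 times that of untreated cells. Region counts were 80946 for IL-4 only and 34803 for untreated only, with 22.6% of IL-4 regions shared against 1.58% for random placements. After thinning to the untreated background, which only removes IL-4 peaks, the unshared regions numbered 46912 and 41901. Midpoints within 1 kb of gene ends made up 11.04% of IL-4 and 2.22% of untreated peaks, midpoints elsewhere in genes 39.1% and 28.2%, and midpoints outside genes 49.9% and 69.5%.

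**Figure D3:**
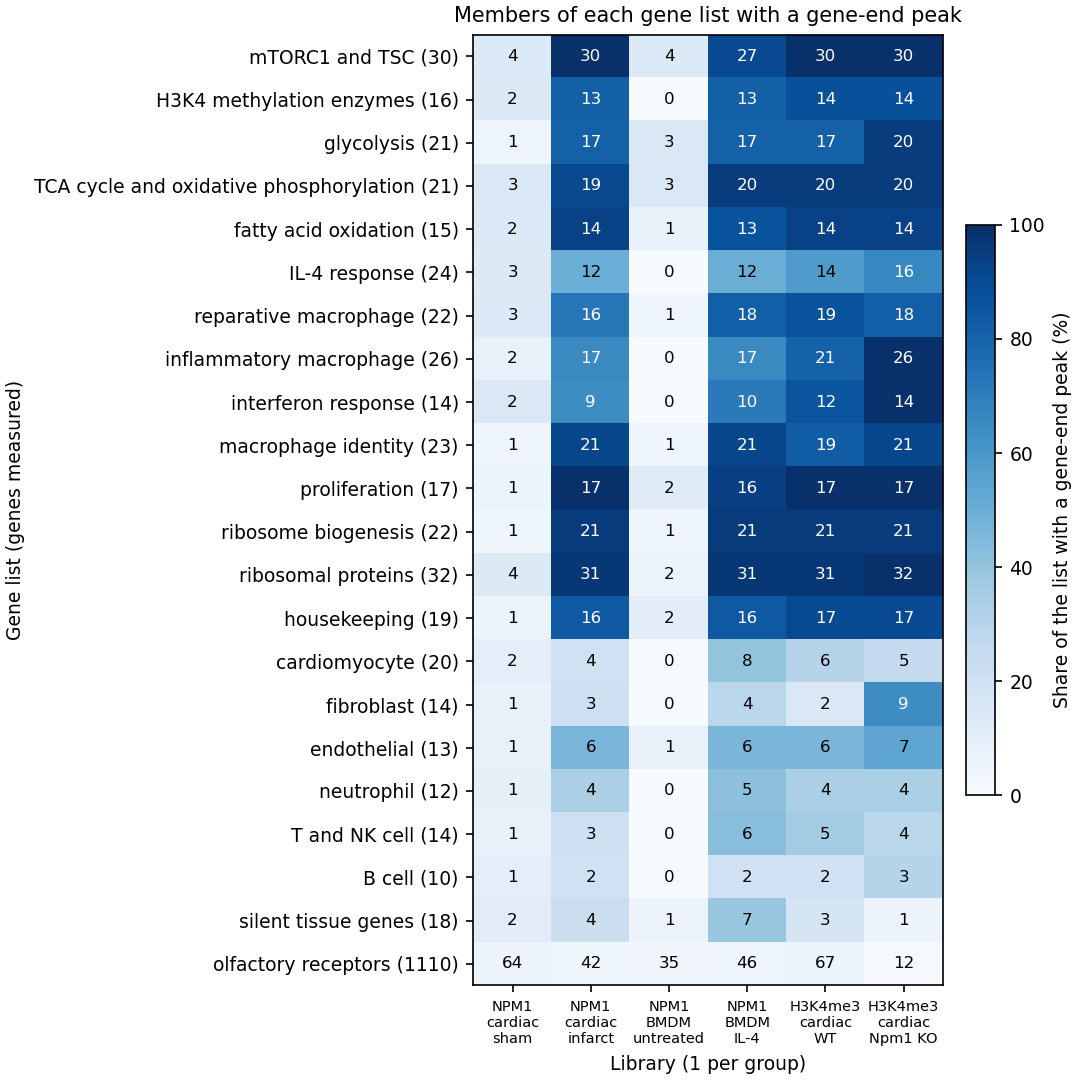
Number of members of each gene list (rows, with the number measured) that had a gene-end peak in each of the 6 libraries (columns), coloured by the share of the list in per cent. The infarct and IL-4 NPM1 columns resemble the H3K4me3 columns, with 30 and 27 of 30 mTORC1 and TSC genes, while the sham and untreated columns hold at most 4 members of any list other than olfactory receptors.

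H3K4me3 in Npm1-knockout and WT cardiac macrophages after infarction was compared to ask which promoters change their mark without NPM1. Most genes kept a gene-end peak: 11685 had one in both libraries, where independent lists would share 7720, 1832 in the knockout library only and 816 in the WT library only. The last 2 counts were 3179 and 63 with −log10 q of 5 or more, and their difference was 346 with a 2.5 kb window. At the genes marked in both, peaks covered more of the 2 kb on either side of the marked end in the knockout, with medians of 1523 bp against 921 bp. Of these genes, 11389 had more covered bases in the knockout. The marked end was the one with the higher fold in either list, so its choice can favour the list with the higher folds. Fibroblast genes (9 of 14 against 2), inflammatory genes (26 of 26 against 21) and glycolysis genes (20 of 21 against 17) had more marked members in the knockout, while the mTORC1 and TSC list was marked at 30 of 30 in both.

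Npm1 kept an H3K4me3 peak in both libraries, with a fold of 7.60 in WT and 7.97 in knockout, which does not test the deletion because the mark lies at the promoter and the deleted part is not given in the sources used here. Tsc1 had a 1236 bp peak with a fold of 4.26 and −log10 q of 6.18 in WT, and a 1490 bp peak with a fold of 8.80 and −log10 q of 77.8 in the knockout. The marked end of Tsc2 was covered over 958 bp in WT and 1620 bp in knockout, that of Kdm5b over 1058 and 1623 bp, and the first end of Mtor over 995 and 1254 bp. Coverage was wider in the knockout at 17 of 17 housekeeping, 31 of 31 ribosomal protein and 30 of 30 mTORC1 and TSC genes marked in both. At 18 macrophage identity genes marked in both, the medians were 816.5 bp in WT and 2062.5 bp in knockout.

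In the inflammatory list, Il6, Il12b, Cd80, Il1b and Cxcl9 had a gene-end peak in the knockout only. The Il6 peak had a fold of 7.78 and −log10 q of 16.6 and the Il12b peak a fold of 5.16 and −log10 q of 7.46, and neither gene had any WT coverage within 2 kb of that end. For Cd80, WT peaks covered 408 bp within 2 kb. In the IL-4 response list (16 of 24 against 14), Arg1, the arginase gene of alternatively activated macrophages, had a knockout-only peak with −log10 q of 9.85 and no WT coverage within 2 kb, and Mrc1, the mannose receptor gene, had one with a fold of 4.03 and 285 bp of WT coverage. Glycolysis genes with a knockout-only peak were Aldoa, Ldha and Hif1a, with −log10 q of 84.2, 5.09 and 4.72, and Aldoa had 866 bp of WT coverage within 2 kb. Ifi44 and Isg15 were the knockout-only members of the interferon list (14 of 14 against 12), and the Isg15 end had 510 bp of WT coverage within 2 kb and a knockout fold of 1.79.

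Itgam, Ctss and Cx3cr1 had knockout-only and Aif1 a WT-only gene-end peak in the macrophage identity list (21 of 23 against 19), though WT peaks covered 591 bp within 2 kb of the Itgam end and 247 bp at Cx3cr1. Timd4, a marker of resident macrophages, had a WT-only peak in the reparative list (18 of 22 against 19), with a fold of 3.57 and −log10 q of 2.97. In the fibroblast list, knockout-only peaks lay at Wt1, Postn, encoding periostin, Acta2, Col1a2, Col3a1, Tcf21 and Mfap5, those of Wt1 and Postn with −log10 q of 23.5 and 13.0. WT peaks covered 481 bp within 2 kb of the Wt1 end and 179 bp at Acta2, and none at Postn. The fibroblast list lay at percentile 99.97 of the net change of matched random lists. Olfactory receptors lay at 0, with 12 of 1110 marked in the knockout and 67 in WT, and the other 20 lists lay within the central 95%. Marked members numbered 7 against 6 of 13 for endothelial, 4 against 4 of 12 for neutrophil, 4 against 5 of 14 for T and NK cell, 3 against 2 of 10 for B cell, 5 against 6 of 20 for cardiomyocyte and 1 against 3 of 18 for silent tissue genes. Knockout and WT counts were equal for the tricarboxylic acid cycle and oxidative phosphorylation list (20 of 21), fatty acid oxidation (14 of 15), H3K4 methylation enzymes (14 of 16), proliferation (17 of 17), ribosome biogenesis (21 of 22) and housekeeping (17 of 19), and ribosomal proteins had 32 against 31 of 32. These counts include weak peaks. With −log10 q of 5 or more, a threshold passed by 12476 genes in the knockout list and 9360 in the WT list, the members numbered 16 against 7 for reparative, 17 against 13 for proliferation, 3 against 1 for cardiomyocyte, 3 against 0 for neutrophil, 3 against 0 for T and NK cell genes and 6 against 3 for olfactory receptors. Fibroblast genes numbered 5 against 0, endothelial 5 against 2, B cell 3 against 1, inflammatory 23 against 12 and IL-4 response 16 against 8. No list had fewer members in the knockout than in WT at this threshold, and silent tissue genes numbered 0 in both. No random lists were drawn at this threshold.

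The leading knockout-only genes without a WT peak within 5 kb were Ada, encoding adenosine deaminase, with −log10 q of 67.5, Slc25a53, Dync2li1, Xk, Ttc26, Zfp933, Stk26 and Akr1c13, with −log10 q down to 58.9. Slc25a53, Xk and Stk26 lie on the X chromosome. The leading WT-only genes were Clca3b, with a fold of 6.38 and −log10 q of 11.4, Rbm20, Gdf2, Pcdha1, Pramel44, Gstm3, Mrgprx1 and Prp2, with −log10 q down to 6.44. The Pcdha1 end is shared by the protocadherin alpha cluster, and Clca3b, Pramel44, Gstm3, Mrgprx1 and Prp2 belong to families of similar genes.

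Of all peaks, 27598 knockout regions and 42999 WT regions had no counterpart, and 47.9% of knockout regions were shared against 3.22% for random placements. The order turned, to 16723 and 3456, for peaks with −log10 q of 5 or more. It also turned, to 11363 and 1749, with a fold of 5 or more. Midpoints within 1 kb of a gene end made up 25.4% of knockout and 19.4% of WT peaks, midpoints elsewhere in genes 46.4% and 42.7%, and midpoints outside genes 28.3% and 38.0%.

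NPM1 and H3K4me3 in WT macrophages after infarction were set side by side to ask how far the NPM1 sites are active promoters. Of the 11072 genes with an infarct NPM1 peak, 9905 (89.5%) also had a WT H3K4me3 peak, where independent lists would share 6324. For the sham NPM1 list the overlap was 1613 of 2384 genes, with 1362 for independent lists. The share of genes with an infarct NPM1 peak was 12.4% without an H3K4me3 peak and went from 49.1% in the fifth of genes with the least H3K4me3 coverage to 95.2% in that with the most. In the sham library these shares were 8.21%, 17.7% and 10.7%.

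**Figure D4:**
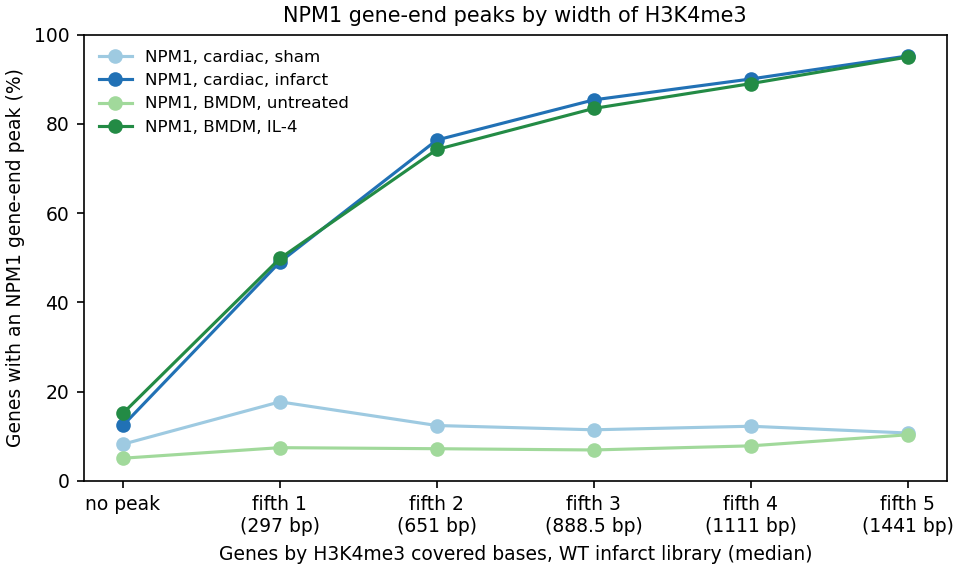
Share of genes with an NPM1 gene-end peak (vertical axis, per cent) in the 4 NPM1 libraries, for genes without an H3K4me3 peak and for the others in 5 equal groups by bases covered in the WT infarct H3K4me3 library (horizontal axis, median bases in brackets). The infarct line goes from 12.4% to 95.2% and the IL-4 line from 15.2% to 95.0%, while the sham line lies between 8.21% and 17.7% and the untreated line between 5.07% and 10.3%.

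The strongest infarct NPM1 peaks at genes with H3K4me3 were at Wls and Lars2, with folds of 42.4 and 27.9, then Wee1, Asmt, Hdgfl2, Brpf1, a chromatin reader, Malt1 and B4galt5. Wls, Lars2 and Asmt had a strong peak in every one of the 6 lists, with −log10 q in the sham list of 2434, 44.6 and 59.0. The infarct peak of Hdgfl2 also touches the end of the neighbouring Ubxn6. Without a WT H3K4me3 gene-end peak, the strongest were Mid1, Plekho1, Rhbdl1, Wt1 and Unc93a2, with folds of 5.13, 6.43, 6.33, 9.91 and 5.99, though WT H3K4me3 peaks lay within 2 kb of that end at all 5. Kdm5b had a gene-end peak of H3K4me3 and none of NPM1, with 1 infarct NPM1 peak elsewhere in the gene, and Npm1, Tsc1 and Mtor had both at the same end. Tsc2 had them at opposite ends.

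NPM1 in cardiac macrophages and in BMDM was compared to ask whether cells of the heart and of culture share its sites. The infarct and IL-4 lists shared 9518 genes, 86.0% of those in the infarct list, where independent lists would share 5673. Npm1, Tsc1, Mtor, Wee1, Malt1, Tle4 and Hspa8 were among them, and Kdm5b was in neither. Tsc2 had a gene-end peak in the infarct and the sham list only. The sham and untreated lists shared 388 genes against 160 for independent lists. Of infarct regions, 51.1% overlapped an IL-4 region, and 20.3% of untreated regions a sham one. The infarct and IL-4 lists were also those with the deeper background, and thinned to the sham and untreated backgrounds they shared 7557 genes. Of the genes in the infarct list, 89.5% had a WT and 91.3% a knockout H3K4me3 gene-end peak. For the IL-4 list these shares were 87.3% and 89.4%. The 86.0% shared by the infarct and IL-4 lists thus does not separate common NPM1 sites from marked promoters in general.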

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

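Counts of genes and regions and the named genes were recomputed with 1 choice changed at a time, list counts only with −log10 q of 5 or more and list percentiles only with unmatched random lists. The H3K4me3-marked gene end, thinning to the shallower background, peaks with q of 0.05 or less, list counts with −log10 q of 5 or more and all alternatives for H3K4me3 covered bases were chosen after the data were seen, and the cause of a changed value was not tested unless stated. With 1 library per group, no replicate could be left out and no paired analysis was made. The planned window around 1 transcription start site per gene was not run, since the gene table gives no strand. The sign of genes gained minus genes lost held in all 10 alternatives for each pair, between 3560 and 8822 for cardiac NPM1, 3386 and 10932 for BMDM NPM1 and 346 and 4723 for H3K4me3. Of the named genes' 3156 values, 2702 were as reported and 454 went to or from a peak in 1 library only. A change of direction could not occur, since each alternative either only removed peaks or narrowed the window, or only widened it. Of 66 list percentiles, 65 stayed inside or outside the central 95% with unmatched random lists. The exception was silent tissue genes for H3K4me3, at 5.87 matched and 0.415 unmatched. All counts of genes and of regions with peaks of q of 0.05 or less, on autosomes or with stitched peaks were within 1.5 times of those reported, as were all with the summit in the window.

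A stricter threshold can only lower the shared counts, while genes and regions of 1 library can go either way. With −log10 q of 5 or more, cardiac NPM1 gene ends numbered 6009 in infarct only, 58 in sham only and 91 in both. BMDM NPM1 gave 6356 in IL-4 only, 16 in untreated only and 71 in both, and H3K4me3 3179 in knockout only and 63 in WT only. NPM1 with H3K4me3 numbered 5708, infarct with IL-4 5311 and sham with untreated 39. Regions numbered 11381 in infarct only, 3326 in sham only and 2527 infarct regions shared, 20175, 2141 and 3110 for IL-4 and untreated, and 16723, 3456 and 12332 for knockout and WT. With a fold of 5 or more, gene ends numbered 3677, 117 and 62 for infarct only, sham only and both, 3419, 33 and 60 for IL-4 and untreated, and 4802, 79 and 6195 for knockout and WT. NPM1 with H3K4me3 numbered 2947, infarct with IL-4 2853 and sham with untreated 34. Regions numbered 4902, 5715 and 1603 for infarct and sham, 6628, 4238 and 2036 for IL-4 and untreated, and 11363, 1749 and 7157 for knockout and WT.

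With a 500 bp window, 837 genes had NPM1 in both infarct and sham and 192 in both sham and untreated. With 2.5 kb these were 3560 and 1059, with 1988 in both IL-4 and untreated and 1237 with WT-only H3K4me3. With the H3K4me3-marked end alone, sham-only genes numbered 290, untreated-only 111, infarct and sham both 723, and sham with untreated 194. That setting also leaves out genes without an H3K4me3 gene-end peak in either list. Equal list lengths gave 492 WT-only H3K4me3 genes, 27115 WT-only regions and 41385 IL-4-only regions. Thinning gave 41908 infarct-only and 46912 IL-4-only regions, and reciprocal overlap 14676 shared IL-4 and 13966 shared knockout regions. Thinning only removes called peaks of the deeper list and adds none, so a sign after thinning does not settle gain or loss of regions. Regions gained minus lost changed sign for cardiac NPM1, to -813 with a fold of 5 or more and -3774 after thinning, from 22212, and was 8055 with −log10 q of 5 or more, 12946 with q of 0.05 or less and 350 with equal list lengths. For H3K4me3 they were -9364 with q of 0.05 or less and went from -15401 to 13267 with −log10 q of 5 or more, 9614 with a fold of 5 or more and 3735 with equal list lengths. With equal lengths this difference only reflects how many regions of 1 list overlap 1 of the other, so that sign says nothing about gain or loss. For BMDM NPM1 it kept its sign but went from 46143 to 5011 after thinning, 18034 with −log10 q of 5 or more, 2390 with a fold of 5 or more and 830 with equal list lengths. The share of genes with more H3K4me3 covered bases in the knockout was 98.97% with −log10 q of 5 or more, 98.9% with a fold of 5 or more, 97.8% with q of 0.05 or less, 98.1% with equal list lengths and 93.8% with stitched peaks.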

Other observations

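The tests of target enrichment in the sham and untreated libraries, of depth and fibroblasts in the H3K4me3 pair and of macrophage identity genes were chosen after the result was seen.

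The sex chromosomes were part of every comparison and are described here apart, with genes and chromosomes chosen after their values were seen. On Y, 10 genes had an H3K4me3 gene-end peak in WT only, 1 in the knockout only and 4 in both. The knockout-only gene was Kdm5d, an H3K4 demethylase gene, whose peak had −log10 q of 17.5, while Ddx3y, Eif2s3y and Uty had H3K4me3 in both libraries. The H3K4me3 lists held 120 peaks on Y in WT and 46 in the knockout. On X, 27.2% of genes with an H3K4me3 peak in either library were knockout-only (110 of 404), against 12.4% on autosomes. NPM1 gene-end peaks were found at 18.5% of X genes and 52.6% of autosomal genes after infarction, and at 21.2% and 53.1% with IL-4. H3K4me3 was also rarer on X, at 30.4% of X and 59.0% of autosomal genes in WT and 41.3% and 63.5% in the knockout. Chromosome Y held 7.03% of the peaks of untreated BMDM (4145), 1.81% with IL-4, 1.57% in sham and 0.148% after infarction.

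A fold of 10 or more in all 6 lists was found in 157 regions, of which 7 overlapped the 1 kb around a gene end. They included the ends of Wls (chromosome 3, 159939294 to 159939785) and Lars2 (chromosome 9, 123461789 to 123462297), with sham folds of 41.6 and 15.3. Among silent tissue genes, the protamine genes Prm1 and Prm2 and the transition protein gene Tnp1, which are expressed in spermatids, had NPM1 peaks after infarction and with IL-4. Prm1 had −log10 q of 15.8 and 42.6 in these lists and no H3K4me3 gene-end peak in either H3K4me3 list.

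Few gene ends had an NPM1 peak in the sham and untreated libraries, which lower depth alone does not explain: infarct summits thinned to 42.5% of their depth still marked 9659 genes, 4.05 times the sham count, and IL-4 summits thinned to 31.4% marked 9036, 6.15 times the untreated count. Sham peaks were found -0.699 percentage points more often at genes in the upper 20% of knockout H3K4me3 fold than at genes without H3K4me3, and untreated peaks 0.685 points more often. By WT fold the sham share was 8.21% at genes without H3K4me3, 18.0% in the lowest of 5 groups and then fell in each group to 10.2% in the highest, while the untreated share was 5.07% without H3K4me3, 7.72% in the lowest group and 10.5% in the highest. An absence of target enrichment in these libraries may account for the low counts, and so may an absence of NPM1 at promoters in resting macrophages, and with 1 library per condition these cannot be told apart.

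H3K4me3 coverage was wider in the knockout library. Deeper sequencing is argued against, since its background pileup was 0.853 times that of WT. Higher enrichment of the whole knockout library may be the source, as 97.47% of genes marked in both lists were wider there, housekeeping genes included, but a genome-wide effect of the knockout would look alike, and with 1 library per genotype these cannot be told apart. More fibroblasts in the knockout sample remain open too: the fibroblast list lay at percentile 99.97, but 5 of its 14 genes had a knockout peak with −log10 q of 5 or more, and Dcn, Lum, Pdgfra and Dpt had no gene-end peak in any list, while macrophages of the infarcted heart may express some of the others and no sort or gate is named in the labels.

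NPM1 peaks lay at gene ends with H3K4me3, and a sampling of H3K4me3-rich promoters in proportion to their strength, as accessible chromatin could give in a transposase assay, predicted a rising share at every step through 5 equal groups of genes by knockout H3K4me3 fold, and the smallest step, into the highest group, was -3.26 percentage points. The prediction was thus not met by that grouping. In groupings that it did not name, the shares rose at every step. They did so by fold in the WT list (53.5% to 94.3%) and by covered bases in the knockout list (47.4% to 92.6%). Since the groupings differ, this explanation cannot be told apart from NPM1 binding. Whether macrophage identity genes may carry more NPM1 than other genes with the same H3K4me3 stayed open as well: 91.3% of the list had an infarct peak, against a median of 56.5% in lists matched on WT fold. This excess was not particular to the list, since ribosomal proteins lay at percentile 99.8, mTORC1 and TSC at 99.9 and proliferation at 98.7 in the infarct library under that matching. Over 4 matchings, 2 libraries and 2 thresholds, 11 of 16 percentiles lay above the central 95%, all those matched on fold among them, while the 4 matched on knockout covered bases lay between 32.4 and 94.6.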
